A study of Mus musculus with 3 samples.

How the data were processed

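Chromatin immunoprecipitation followed by sequencing was used to map Foxd3, a forkhead transcription factor, in mouse embryonic stem cells. The cells carried an added Foxd3 with a Flag and an HA epitope tag, delivered by lentivirus into the LF2 line, and were grown with serum and LIF without feeder cells, per the labels' protocols. The series has 3 samples: 1 precipitation with an anti-HA antibody, 1 with an anti-Flag antibody, and 1 input of total genomic DNA. Per the labels' protocols, chromatin was sonicated, fragments were selected on an agarose gel, and libraries were amplified by PCR and read on an Illumina Genome Analyzer.

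The authors deposited 1 peak list per antibody, as genomic positions in base pairs with no other value. Tested on the files, each list has 3 columns (chromosome, start and end) and holds no height, fold enrichment, p-value or read count. Each peak is therefore present or absent, with a width, and the sequencing depth behind it is unknown. The build is mm9, per the submitters' processing notes. The aligner, the peak caller, its threshold and the way the input entered the calls are not given in the sources used here. The input was not analysed here. A threshold set separately for each library decides which weak sites are listed, so a peak in 1 list only is not evidence that the other library had no signal there.

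Starts were converted from 0-based to 1-based positions for printing. Peaks were called shared when they overlapped by at least 1 bp. Overlap counts were checked against bedtools 2.31.1 and were equal. To measure chance, the HA peaks of each chromosome were shifted together around the chromosome 100000 times, which keeps their widths and spacing. The chromosome length was taken as the largest peak end in either list. This one-sided permutation test, the two-sided permutation tests of median widths, and those of correlations each used 100000 resamples, so 1e-05 is the smallest p they can give. Shares have 95% Wilson intervals, peak densities have exact Poisson intervals, and differences of medians have intervals from 2000 bootstrap resamples. These cover counting error only. Peaks of 1 library are not replicates, and with 1 library per antibody no test here measures variation between cultures. Benjamini-Hochberg adjustment was applied over the 20 chromosomes of each list for widths, over the 2 lists for the X chromosome, and over the 8 half-chromosome tests.

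The analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9. The code was tested on simulated data. All 1000 planted overlaps were recovered, and 4 of 100 pairs of independent lists gave p below 0.05. A planted width shift of 100 bp was called in 100 of 100 simulations, against 5 of 100 with no shift. The width simulations used larger groups of peaks than the tests by chromosome. The independent lists were placed at random, without the clustering of the real lists. Neither check covers those cases.

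The design, the regions to name and most alternatives were fixed before the data were examined. The regions named are the 10 shared regions with the best mean width rank in both lists, the 5 widest unshared peaks of each list, and the 3 widest peaks of each list. The widths and densities by chromosome, the split of chromosomes 8 and 14 at their middle, the order of lines, the distances of unshared peaks and the X chromosome test for each list were added after the data were seen. Width stood in for a peak value, as had been set for lists without one. The alternatives varied the overlap that counts as shared, the number of peaks kept, the model of chance and the chromosomes included. The planned comparisons of peak heights, the search for forkhead and other motifs, the distances to transcription start sites and the tests of gene lists (naive, core and primed pluripotency, germline, Nodal signalling, germ layers, neural crest, trophectoderm, chromatin remodelling and housekeeping) were not run. They need peak values, or a genome and annotation in mm9. The gene table at hand is on another build, GRCm38.p6, so no peak was assigned to a gene.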

Results

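Binding of tagged Foxd3 was profiled in mouse embryonic stem cells by precipitating the same fusion protein through either of its epitope tags. Using both tags asks which sites are recovered whichever of them is pulled. The HA list held 3406 peaks covering 2057 kb, with a median width of 547 bp (interquartile range 426 to 714 bp). The Flag list held 4569 peaks covering 2557 kb, with a median width of 490 bp (369 to 666 bp). Both lists reached chromosomes 1 to 19 and X, and no peak overlapped another of its own list. Each antibody is represented by 1 library, and read depth is not recorded in the lists.

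Most HA sites were also Flag sites. Of the HA peaks, 2496 touched a Flag peak, which is 73.3% (95% Wilson interval 71.8 to 74.7). In the other direction 2497 Flag peaks touched an HA peak, or 54.7% (53.2 to 56.1). That left 910 peaks in the HA list alone and 2072 in the Flag list alone. Shifting the HA peaks along their chromosomes gave a mean of 7.24 shared peaks and at most 181, so the observed overlap exceeded every shift (one-sided permutation test, p = 1e-05, the smallest possible). Shifts close to 0 were allowed, and these can nearly restore the true alignment of a chromosome, so 181 overstates chance. The highest count was 22 with random positions and 30 with shifts of 20 kb to 1 Mb. These models of chance move peaks without regard to regions that any precipitation might recover. The excess therefore shows that the lists agree, not that the shared sites are bound by Foxd3. No precipitation from cells without the tagged protein was analysed here. By length the 2 lists had 1305 kb in common, 39.4% of the 3309 kb covered by either.

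The shared sites lay at nearly the same positions. There were 2474 pairs in which 1 HA peak met 1 Flag peak. Their centres were a median of 50.5 bp apart, and 76.3% of pairs had centres within 100 bp. In the median pair the shorter peak lay entirely inside the longer one. Median widths in these pairs were 565 bp for HA and 547 bp for Flag, and the Flag peak was the wider in 1200 pairs and the HA peak in 1269. Widths were correlated across pairs (Spearman rho = 0.67, Pearson r = 0.61, permutation p = 1e-05 for each). Without pairs holding the widest 1% of either list, rho was 0.66 and r was 0.64. This is a correlation across sites, which are not independent replicates.

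Sites seen with both antibodies were wider than sites seen with 1. In the HA list the median width was 567 bp for shared and 498 bp for HA-only peaks, a difference of 69 bp (95% bootstrap interval 50 to 90.5 bp, two-sided permutation p = 1e-05). In the Flag list the medians were 548 bp and 407 bp, a difference of 141 bp (130 to 157 bp, permutation p = 1e-05). The shared share fell from 78.3% in the widest decile of HA peaks to 55.9% in the narrowest. Among Flag peaks it fell from 73.1% to 18.2%. A wider peak meets another more easily by chance, but chance overlap was 7.24 peaks over the whole list.

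The order of lines in the deposited lists carried a similar gradient, although the lists do not state what the order is. In the HA list 99 of the first 100 lines were shared, and the share was 97.1% in the first decile and 37.4% in the last. The Flag list began differently. Its first 27 lines were all Flag-only, as were 90 of its first 100. Its shared share was 63.7% (59.2 to 68.0) in the first decile, 74.6% (70.4 to 78.4) in the second and 30.5% in the last. The opening Flag line was an 832 bp peak at chromosome 4, 139814668 to 139815499, and the second a 725 bp peak at chromosome 7, 6362653 to 6363377 (mm9).

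**Figure D1:**
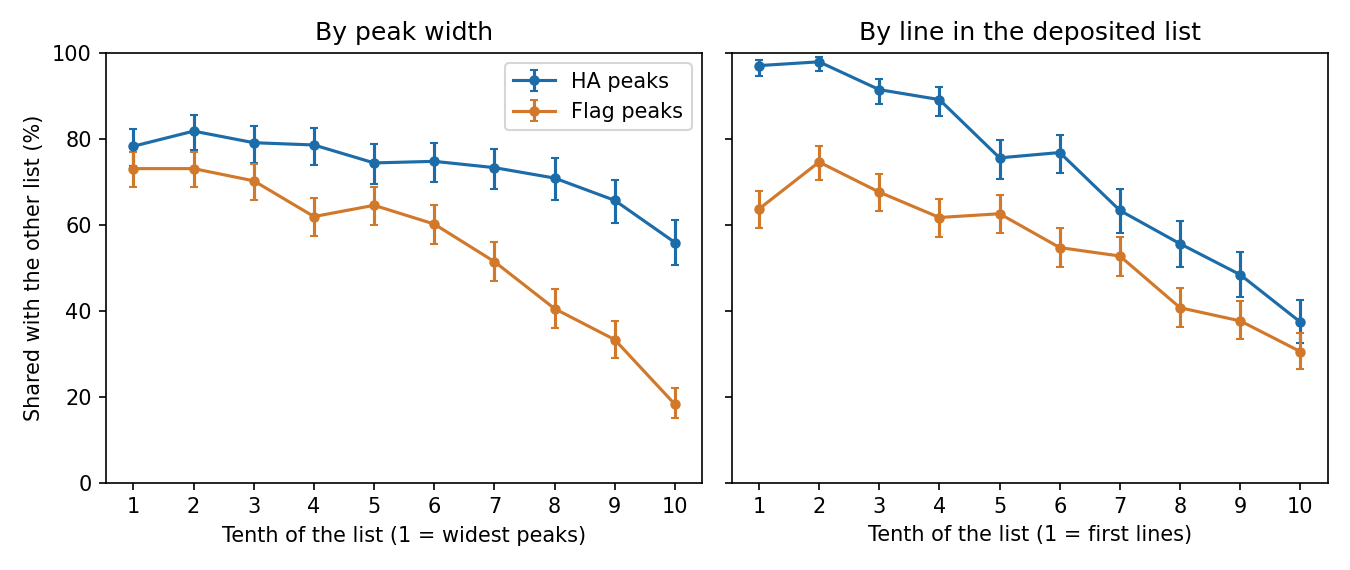
Share of peaks (%, vertical axis) that overlapped a peak of the other list by at least 1 bp, for each decile (1 of 10 equal parts) of the HA list (blue) and the Flag list (orange), ordered by width (left) or by line in the deposited list (right); bars are 95% Wilson intervals. By line, the first decile of HA peaks was 97.1% shared and the first decile of Flag peaks 63.7%.

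The 10 widest shared regions, by mean width rank in both lists, fell on 5 chromosomes. Chromosome 14 held 4 of them (mm9 76914302 to 76917223, 99738655 to 99741080, 65213171 to 65215170 and 73637476 to 73639461) and chromosome 9 held 3 (78222149 to 78223917, 58126377 to 58128135 and 110849111 to 110850892). The others were at chromosome 11, 3070291 to 3072663, chromosome 6, 148939797 to 148941978, and chromosome 4, 133371297 to 133373102. The region on chromosome 11 ranked first, with an HA width of 1835 bp and a Flag width of 2373 bp. The region at 76.9 Mb of chromosome 14 came next, with 1624 bp in HA and 2515 bp in Flag. None of these positions was assigned to a gene, exon or intron, because no mm9 annotation was used here.

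The widest HA peak was 2121 bp long, at chromosome 14, 99723451 to 99725571. It was followed by a 2056 bp peak at chromosome 14, 119111787 to 119113842, and a 2041 bp peak at chromosome 15, 7065191 to 7067231. All 3 were shared with Flag. The widest Flag peak spanned 5241 bp at chromosome 7, 3217500 to 3222740, and was shared with HA. A 2985 bp Flag peak at chromosome 17, 29627970 to 29630954, had no HA counterpart, and a 2664 bp peak at chromosome 11, 3075805 to 3078468, had one.

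Some wide peaks had no overlapping peak in the other list. This does not make each of them a separate site of 1 antibody. The 1937 bp HA-only peak on chromosome 11 and the 1868 bp HA-only peak on chromosome 14 lay inside groups of nearby HA peaks, as grouped under Other observations. On chromosome 11 the group from 3069416 to 3100146 had 4 of its 9 HA peaks shared, and it spanned the first-ranked shared region. On chromosome 14 the group from 76894425 to 76929210 had 3 of its 4 HA peaks shared. The widest HA-only peaks measured 1937 bp (chromosome 11, 3081075 to 3083011), 1868 bp (chromosome 14, 76906971 to 76908838), 1614 bp (chromosome 13, 23492525 to 23494138), 1572 bp (chromosome 14, 79133214 to 79134785) and 1508 bp (chromosome 8, 126740554 to 126742061). After the chromosome 17 peak, the widest Flag-only peaks measured 2326 bp (chromosome 8, 119196313 to 119198638), 2280 bp (chromosome 6, 136439169 to 136441448), 2097 bp (chromosome 11, 62323754 to 62325850) and 2066 bp (chromosome 2, 20593192 to 20595257).

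Unshared peaks lay beside sites of the other antibody more often than shifted peaks did. Of the 910 HA-only peaks, 130 (14.3%, 12.2 to 16.7) had a Flag peak within 10 kb, against a mean of 30.7 and a maximum of 65 over circular shifts (one-sided permutation p = 1e-05). Of the 2072 Flag-only peaks, 168 (8.11%, 7.01 to 9.36) had an HA peak within 10 kb, against a mean of 51.6 and a maximum of 88 (permutation p = 1e-05).

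Peaks were unevenly spread over chromosomes in both lists. Chromosome 8 had 1.95 HA peaks per Mb (95% Poisson interval 1.72 to 2.21) and 2.52 Flag peaks per Mb (2.25 to 2.80). Chromosome 14 had 1.80 (1.57 to 2.05) and 2.30 (2.04 to 2.59), and chromosome 11 had 1.77 (1.54 to 2.03) and 2.54 (2.26 to 2.84). The X chromosome had the lowest density in each list, at 0.94 HA (0.79 to 1.10) and 1.06 Flag peaks per Mb (0.91 to 1.23), followed by chromosome 12 at 0.98 and 1.35. Peaks were also wider on chromosomes 8 and 14 than on the other autosomes. On chromosome 8 the median exceeded that of the other autosomes by 92 bp in HA (permutation test, adjusted p = 0.0002) and by 49 bp in Flag (adjusted p = 0.0118). On chromosome 14 it did so by 62 bp in HA (permutation test, adjusted p = 0.0141) and by 74 bp in Flag (adjusted p = 0.0004). No other chromosome passed 0.05 in either list.

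**Figure D2:**
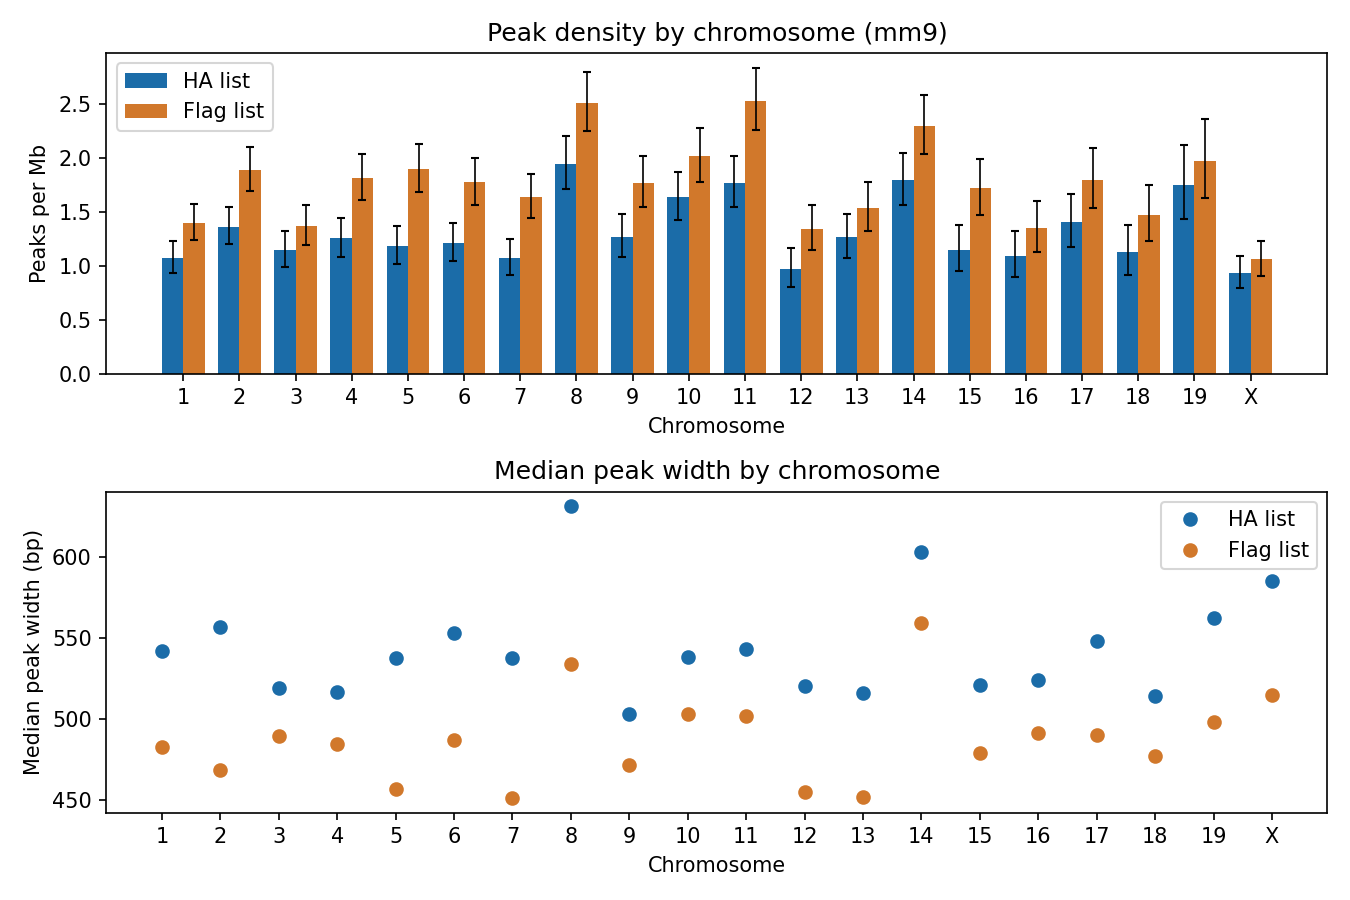
Peaks per Mb (top; bars are exact 95% Poisson intervals) and median peak width in bp (bottom) on each chromosome, for the HA list (blue) and the Flag list (orange). Chromosome 8 had 1.95 HA and 2.52 Flag peaks per Mb, and chromosomes 8 and 14 had the widest median peaks in both lists.

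The shared share differed over the 20 chromosomes in the Flag list, while in the HA list that test was not passed. X, tested on its own after the data were seen, had a higher share than the autosomes in each list. The lists were not tested against each other. Shared shares of Flag peaks ranged from 44.4% (38.4 to 50.6) on chromosome 7 and 45.3% (39.7 to 51.1) on chromosome 5 to 66.1% (57.2 to 74.0) on chromosome 19 and 72.4% (65.3 to 78.5) on X. The low shares lay where the Flag list was longer relative to the HA list. Chromosomes 7 and 5 had 1.52 and 1.61 Flag peaks per HA peak, against 1.12 on chromosome 19 and 1.14 on X. This relation follows largely from the counts, since 2474 of the 2506 overlapping pairs were 1 to 1. The Flag share is then close to the HA share divided by Flag peaks per HA peak. Differences in Flag share between chromosomes thus reflect in part the relative lengths of the lists. Permuting the shared labels over the 20 chromosomes gave p = 1e-05 for Flag (chi-square 80.1) and p = 0.162 for HA (chi-square 24.99). On X, 82.4% of HA peaks were shared (75.5 to 87.6), compared with 72.9% on the autosomes (Fisher's exact test, two-sided, p = 0.00872, adjusted p = 0.00872). For Flag the autosomal share was 53.9% (52.5 to 55.4; Fisher's exact test, adjusted p = 2.38e-06). X had the highest share of the 20 chromosomes in each list. The adjustment covered the 2 lists and not the choice of X among the chromosomes, so the HA difference remains uncertain.

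Within chromosome 14 the dense and wide peaks lay past its middle at 61.4 Mb. There were 142 HA peaks with a median width of 670 bp, 129 bp above the other autosomes (86 to 161.5 bp), and 185 Flag peaks at 625 bp, 140 bp above (88.0 to 205.0 bp). Each had an adjusted permutation p of 4e-05. Only chromosomes 8 and 14 were split, after the data were seen, so these tests partly restate the widths of the whole chromosomes. The parts of a chromosome were not tested against each other. Before the middle there were 79 HA peaks at 492 bp and 98 Flag peaks at 470.5 bp. They differed from the other autosomes by -49 bp (-77 to 16 bp) and -14.5 bp (-64.0 to 25.5 bp), with adjusted permutation p values of 0.131 and 0.608. The bin from 70 to 80 Mb held 42 HA and 52 Flag peaks, against a median of 12 HA and 16 Flag peaks per 10 Mb bin on the other autosomes. Not every bin past the middle was dense or wide. From 80 to 90 Mb there were 7 HA and 13 Flag peaks, with median widths of 458 and 456 bp. Chromosome 8 was also denser past its middle at 65.6 Mb, with 160 HA peaks there against 96 before it (2.44 and 1.46 per Mb) and 208 Flag peaks against 122 (3.17 and 1.86 per Mb). Its peaks past the middle were wider by 101.5 bp in HA (47.5 to 163.0 bp, adjusted permutation p = 8e-05) and by 51 bp in Flag (31.0 to 106.0 bp, adjusted p = 0.0118). Peaks before it differed by 54 bp in HA (23.5 to 118 bp, adjusted permutation p = 0.0716) and by 34.5 bp in Flag (-31.5 to 85.5 bp, adjusted p = 0.198).

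**Figure D3:**
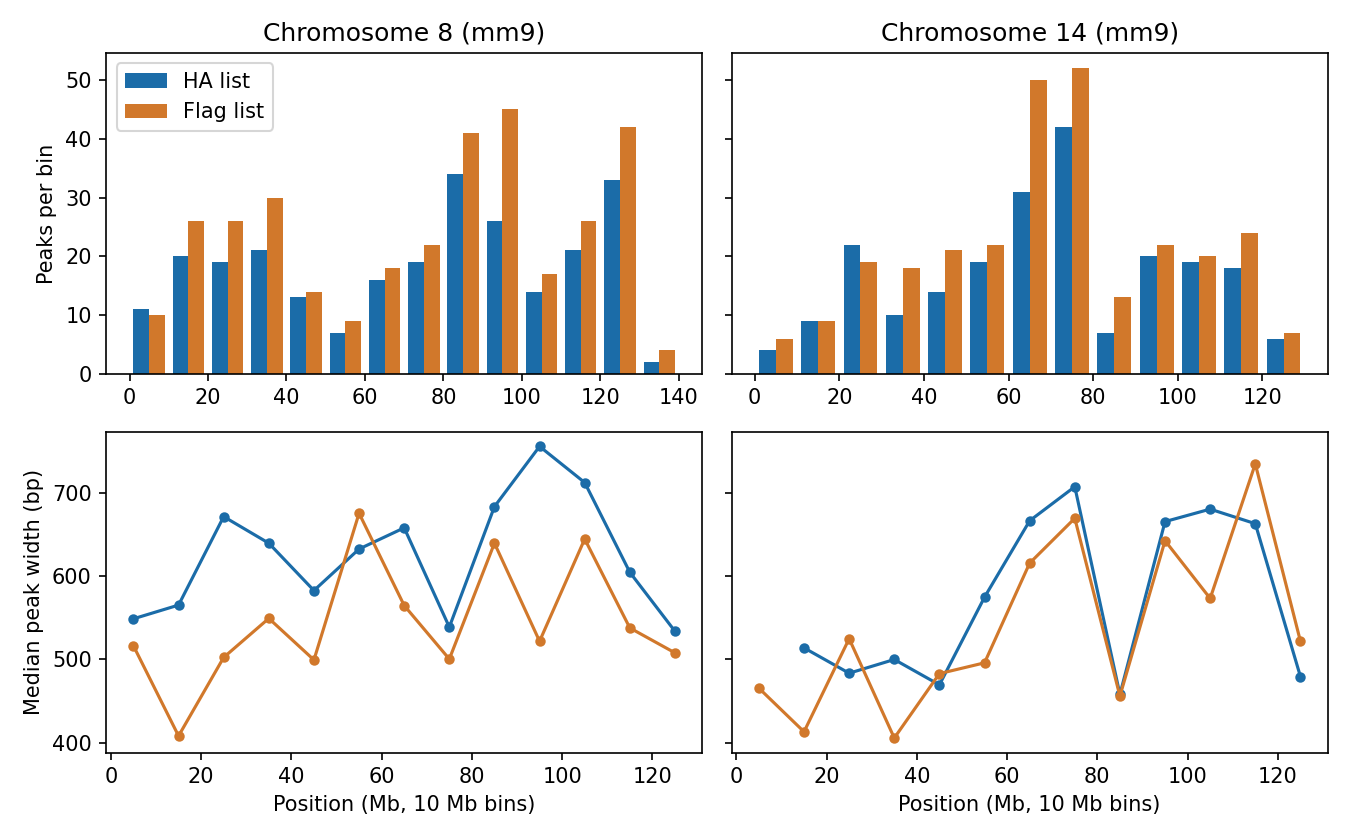
Peaks per 10 Mb bin (top) and their median width in bp (bottom, bins with at least 5 peaks) along chromosomes 8 and 14 in mm9 coordinates, for the HA list (blue) and the Flag list (orange). On chromosome 14 the bin from 70 to 80 Mb held 42 HA and 52 Flag peaks. Median width was larger over all peaks past the middle, though not in every bin.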

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

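The number of shared HA peaks exceeded chance (permutation p = 1e-05) under every overlap rule, peak subset, chromosome set and chance model tried. It stayed within 1.5 times the main count of 2496 except where lists were shortened: 1118 in the wider 50% of each list, 207 in the widest 500 and, in a setting chosen after seeing the data, 1224 in the first 50% of the lines. The shared shares moved beyond their intervals in 3 settings. Requiring 50% of each peak gave 69.7% of HA and 52.0% of Flag peaks, the wider 50% of each list gave 65.6% and 49.1%, and the widest 500 gave 41.4% of each. Fewer candidate partners remain by construction in the shortened lists. The other 35 values, of 44 in all with an alternative, kept their direction and side of the threshold or stayed inside their interval. Of these, the settings without chromosomes 8 and 14, without the first 100 Flag lines (72.99% of HA and 55.65% of Flag peaks), with shifts of 20 kb to 1 Mb, and all of the width correlations were chosen after seeing the data. Alternatives set beforehand for peak heights, motifs, start sites and gene lists were not run. Leaving out a replicate was not possible, and no paired analysis was possible because each antibody has 1 library. Read depth is unknown, so no limit could be set on signal below the authors' threshold.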

Other observations

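Some sites came in close groups. Linking peaks less than 12.5 kb apart gave 34 groups of 3 or more HA peaks (121 peaks) and 48 groups of Flag peaks (162 peaks), against a mean of 1.14 and 2.59 and a maximum of 6 and 10 groups in 1000 random placements on the same chromosomes. The fullest group in both lists lay near the start of chromosome 11 (mm9), with 9 HA peaks between 3069416 and 3100146 and 7 Flag peaks between 3054527 and 3097186. Another lay near the start of chromosome 7, with 5 HA peaks between 3193118 and 3218190 and 6 Flag peaks between 3193108 and 3222740. On chromosome 3, 4 HA peaks between 34644043 and 34660684 were all shared, within a group of 6 Flag peaks from 34633760 to 34660715. A group of 4 HA and 4 Flag peaks, all shared, spanned 76393425 to 76404881 on chromosome 14, and 5 HA peaks spanned 91515425 to 91545816 on chromosome 8. A group of 4 HA peaks on chromosome 16, 22402652 to 22416732, had no Flag counterpart.

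All tests of the patterns below were chosen after the result was seen except the test for packed sites among the leading Flag peaks.

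The Flag list opens with sites that the HA list lacks. The test for packing argues against sites packed in a few clusters, since 6.02% of the 166 Flag-only peaks in the first decile of lines lay within 100 kb of another. Sites just under the HA threshold stay open: 36.3% of that decile was Flag-only, against 25.4% of the second (21.6 to 29.6), but the lists give no peak strength to show that the lines run from strong to weak. Line number and width were related over the Flag list (Spearman rho = -0.23, permutation p = 1e-05). The Flag-only peaks of the first decile had a median width of 521 bp, against 692 bp for its 291 shared peaks. That median pools the 90 Flag-only peaks of the first 100 lines with those of later lines, so it does not give the width at the head. The first 5 lines measured 832, 725, 778, 846 and 427 bp. DNA recovered by the Flag antibody without Foxd3 is a candidate explanation that was not tested, because no precipitation from cells without the tagged protein was analysed here.

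Chromosomes 8 and 14 carry more and wider peaks with both antibodies. On chromosome 14 the part before the middle had width differences with upper bounds of 16 bp in HA and 25.5 bp in Flag. These lay below the 62 and 74 bp of the whole chromosome, so wider peaks were not seen along all of it. This cannot decide on a gain of the whole chromosome. The whole includes that part, and its own intervals were 14 to 98.0 bp in HA and 34.0 to 118.0 bp in Flag. Whether a gained copy widens peaks was not tested. For chromosome 8 the bounds before the middle (118 and 85.5 bp) did not exclude its 92 and 49 bp. For density the share of bins left a gain of either whole chromosome open. On chromosome 8, 84.6% of 10 Mb bins in HA and 76.9% in Flag exceeded the median bin of the other autosomes. On chromosome 14, 66.7% and 75% did. A whole gain alone was predicted to leave overlapping Poisson intervals before and past the middle, and none overlapped. On chromosome 14 there were 1.29 HA peaks per Mb before it (1.02 to 1.60) and 2.31 past it (1.95 to 2.73). For Flag these were 1.60 (1.30 to 1.94) and 3.01 (2.59 to 3.48). On chromosome 8 they were 1.46 and 2.44 in HA and 1.86 and 3.17 in Flag. Density was therefore not even along either chromosome. No other autosome was split, and density varied along others too: 10 Mb bins of chromosome 4 held from 1 to 29 HA peaks. The unequal parts thus cannot decide on a gain. A few dense stretches stay open too: without the 3 densest bins chromosome 8 had 1.61 HA and 1.996 Flag peaks per Mb and chromosome 14 had 1.36 and 1.69, above the median of the other autosomes treated the same way (0.974 and 1.31) but, apart from chromosome 8 in HA, below the highest of them (1.48 and 2.12). A gain of part of a chromosome, or more regulatory sites there, may contribute and was not tested, because neither the input reads nor an mm9 annotation was analysed here.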
